A study of Ambystoma mexicanum with 21 samples.

How the data were processed

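Gene expression was measured on 21 one-colour Agilent arrays, 3 for each of 7 groups, in Cherry-positive connective-tissue cells sorted from axolotl forelimbs. The groups were the uninjured limb and the regenerating limb on 6 days after amputation, 1, 3 and 5 and then 7, 10 and 14 days (dpa). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, each sample pooled 4 to 6 animals of one clutch, and the 3 replicates of a group came from separate batches of animals. The p-values therefore set a change against the spread between such pools within a group, taken as independent. That spread was estimated over all 7 groups together and not from the 2 groups compared alone. Every group also had replicates that shared a slide, so part of that spread is one within a slide. The correlation of arrays within a slide was estimated at 0.497, and the main fit did not allow for it. Per the labels' protocols, total RNA came from 150000 to 250000 cells and 45 ng of it was labelled with Cy3. The custom array held 415996 probes, with 3 sense probes and 1 antisense probe for each transcript of known strand, and 20839 of the probes were carried over from an older design based on expressed sequence tags and complementary DNA.

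The scanner files held spot intensity on a linear scale, per the file headers made with Feature Extraction 10.7.3.1. The processed signal intensity was background-subtracted and spatially detrended, and was multiplicatively detrended on 18 of the 21 arrays, per the file headers. No scaling between arrays was recorded there. The deposited table of the whole series held log2 values, and the submitters' processing notes name limma 3.58.1 without a role. Set against the scanner values, its columns equalled the log2 processed signal minus the array's 75th percentile, with each probe centred on its median over the 21 arrays. All 415994 rows had a median within 1e-06 log2 of 0. The scale, centring and direction were therefore found from the values. Its row names were offset by 2 probes from the scanner order. With that offset 415886 of 415994 rows matched on all arrays within 0.01 log2, against 359 without it. The rows were used through the offset, never through their names. The medians of its columns were -0.10, 0.01 and -0.10 for uninjured replicates 1, 2 and 3. They were -0.17, -0.13 and -0.10 at 1 dpa, 0.24, 0.19 and 0.05 at 3 dpa, and 0.11, 0.31 and 0.12 at 5 dpa. At 7 dpa they were -0.13, -0.16 and 0.14, at 10 dpa 0.25, -0.00 and -0.10, and at 14 dpa -0.05, -0.12 and -0.11.

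From the scanner files, log2 of the processed signal minus each array's 75th percentile over the 415996 non-control probes was computed. Spots marked as non-uniform outliers were set to missing (1820 spots, of which 1610 on array 3 of 14 dpa and 3 to 31 on each other array), and no non-control spot was saturated. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 233883 probes. A further 101850 probes were above background on none of the 21 arrays. Group means were fitted over all 21 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that the 7 groups shared 1 estimate of the spread per probe. The residual degrees of freedom were 14 and the prior degrees of freedom 3.97. P-values were adjusted within each contrast by Benjamini-Hochberg, and a probe was called at an adjusted p under 0.05. A moderated F test over the 6 contrasts against the uninjured limb gave the probes changed on any day. Arrays and figures were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

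The files name probes by ID only, and 0 of the 415996 IDs matched the 135668 genes of the reference table for assembly UKY_AmexF1_1. Results are therefore given for probes. Sense and antisense probes were not told apart, and several probes can measure 1 transcript, so a count of probes is not a count of genes. Tests of gene lists, of markers of other cell types and of PRRX1, the alternative of averaging the sense probes of a gene, and the naming of genes by symbol were planned but need gene names and were not run. Because no cell-type markers could be read, the purity of the sorted cells was not checked. The rule for named genes was narrowed, after the data were seen, to 4 probe IDs, those with the largest fitted rise and the largest fitted fall at 1 and at 14 dpa. The fitted changes use values below background, so this rule does not show that no other probe changed more. Each had to pass the adjusted p threshold with its 3 values beyond the 3 uninjured values. Where a probe was not well above background on any array of the dimmer group, its fold is a lower bound. It sets the bright group's mean against the mean of, per array, the higher of the probe's own value and the lowest signal well above background.

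The comparison was tested on simulated data for 1 dpa against the uninjured limb over 233883 probes, with 50 changed at each of 4 fold sizes. At 2-fold 4 of 50 changed probes were recovered, at 4-fold 36 of 50, at 8-fold 42 of 50 and at 16-fold 45 of 50, and 7 unchanged probes were called there. These shares hold where few probes change, which makes the adjusted p stricter than in the data, where 30834 of the 42540 probes called at 1 dpa changed at least 2-fold and the others less. For the counts that combine comparisons, unchanged groups were simulated over the 21 arrays with each probe's fitted spread. Lists as long as the real ones were taken from them by the moderated t, since an adjusted p calls almost no unchanged probe. This simulation was chosen after seeing the data. The number of arrays limits the precision.

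The tests, samples and covariates of the single-day and successive-day counts, and most alternatives, were chosen before the data were examined. Those alternatives were other thresholds, normexp background correction with an offset of 50, quantile normalization, median centring, the deposited log2 table, other filters on dim probes, a trended and robust variance, a fit of only the 2 groups compared, slide as a random block, a replicate block, and each replicate left out. Normexp was planned on the mean spot signal and used the median spot signal, the column the files hold. Chosen after seeing the data were spike-in brightness as a covariate, a term for the late-scanned slides, the arrays scanned early taken alone, slide as a fixed block, array 3 of 14 dpa left out, and, apart from the F test, all counts that combine several days. The split into 6 slides scanned early (12 arrays) and 5 scanned late (9 arrays) was also placed after the spike-in levels were seen. Brightness was the mean log2 signal of 7 bright spike-in probes.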

Results

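Axolotls are salamanders that regrow an amputated limb. Connective-tissue cells were followed over the first 14 days of that process in animals whose Prrx1 regulatory sequence drives an inducible Cre recombinase that switches on the red protein Cherry. The right forelimb of animals 9 cm long was amputated through the lower arm, and Cherry-positive cells were sorted from the blastema together with tissue 2 mm behind the amputation plane. The question was how expression on each of 6 days, from 1 to 14 days post amputation (dpa), differed from that in the uninjured limb. The labels place the uninjured tissue in the upper arm in one field and in the lower arm in another. Its position along the limb is therefore not settled. If it came from the upper arm, every comparison with the uninjured limb would hold a difference of position, which cannot be told apart from regeneration. Each of the 7 groups had 3 arrays. Between 155522 and 242573 of the 415996 probes were well above background on an array.

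Expression changed over the course for 168838 of 233883 tested probes (72.2%) by the moderated F test of limma at an adjusted p under 0.05. Uninjured and 1 dpa arrays lay together on one side of the first principal component, and the 3 and 5 dpa arrays lay on the other side. That component held 34.7% of the variance. The former arrays were all scanned early and the latter all late, so the component alone cannot tell day from scanning. Within 7, 10 and 14 dpa the late-scanned array lay further toward the side of 3 and 5 dpa than its group mates. The second component held 22.6% of the variance and ran from the 3 dpa arrays at 213 to 223 to the 14 dpa arrays at -315 to -269. Array 3 of 14 dpa stood apart, with an SD of 1.00 log2 from the mean of its group mates, against 0.37 to 0.76 for the other 20 arrays. The lowest correlation of 2 arrays of one group over all probes was 0.880.

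**Figure D1:**
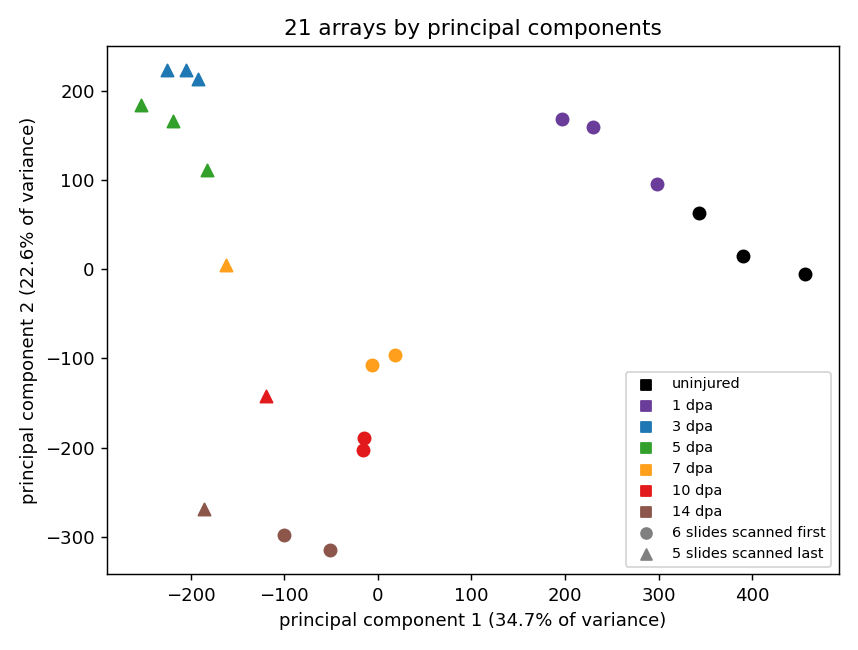
The 21 arrays by their scores on principal components 1 (34.7% of the variance) and 2 (22.6%), both without units, coloured by day and with circles for arrays on the 6 slides scanned first and triangles for the 5 scanned last. The 3 dpa arrays lie between 213 and 223 on component 2 and the 14 dpa arrays between -315 and -269, and within 7, 10 and 14 dpa the late-scanned array lies to the left of its group mates.

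At 1 dpa, 27683 probes were higher and 14857 lower than in the uninjured limb, together 18.2% of those tested. A change of at least 8-fold was called for 2211 higher and 313 lower probes. CUST_88938_Unique, the probe with the largest fitted rise, was above background on none of the uninjured arrays and at a level of 7.94 ± 0.06 log2 relative to the array's 75th percentile at 1 dpa (SD, n = 3), at least 1683-fold higher (adjusted p = 7.63e-14). CUST_246009_Unique, the probe with the largest fitted fall, was at 1.14 ± 0.87 log2 in the uninjured limb and above background on no array after amputation, at least 18.2-fold lower at 1 dpa (adjusted p = 8.96e-08). These bounds hold for the processed signal. After normexp, whose offset narrows the differences of dim probes, the fitted log2 changes of these probes were 7.92 and -2.05. The 3 values of one group lay wholly beyond those of the other for 34.7% of probes. Chance gives 10% only if all arrays compared are independent. Every group had replicates that shared a slide, and arrays within a slide correlated at 0.497. Such shares, here and on the later days, therefore cannot tell a difference of day from one of slide. No excess over 10% is claimed. On the one slide that held an array of both groups, 30487 of 32266 probes called without those 2 arrays (94.5%) moved in the same direction. Slide as a fixed block estimates the change from those 2 arrays alone, 1 against 1, with 7 residual degrees of freedom from the whole fit. It gave 17339 probes higher and 18230 lower, a higher share of 48.7% against 65.1%. These counts describe that pair of arrays and not the 3 pools of each group.

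At 3 dpa, 64918 probes were higher and 58493 lower than in the uninjured limb, 52.8% of those tested. At least 2-fold changes were called for 49001 higher and 47498 lower probes, and at least 8-fold changes for 5525 and 2012. CUST_88938_Unique was still at least 233-fold above the uninjured level (adjusted p = 2.65e-12). CUST_24191_Unique, well above background in both groups, was 6.95-fold lower (log2 change -2.80, SE 0.48, adjusted p = 0.000107). The groups did not overlap for 59.8% of probes. All 3 dpa arrays were on slides scanned late and were dimmer, with a 75th percentile of 33.4 to 51.3 against 59.0 to 79.0 in the uninjured limb, and with spike-in brightness as a covariate 58509 probes were higher and 40045 lower. With a term for the late-scanned slides, estimated within 7, 10 and 14 dpa, 53723 were higher and 27531 lower. Higher probes made up 52.6% of the calls, against 70.3% with arrays centred on the median, which raised the median change by 0.37 log2, and 62.9% after normexp, which raised it by 0.19, while quantile normalization turned the majority (58738 higher and 58860 lower).

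At 5 dpa, 60890 probes were higher and 57623 lower than in the uninjured limb, 50.7% of those tested. At least 8-fold changes were called for 4968 higher and 2390 lower probes. CUST_88938_Unique was at least 33.3-fold above the uninjured level (adjusted p = 2.72e-10), and CUST_24191_Unique was 26.8-fold lower (log2 change -4.74, SE 0.48, adjusted p = 3.14e-07). The groups did not overlap for 58.3% of probes. The 5 dpa arrays were also all scanned late, with a 75th percentile of 28.3 to 39.4, and with spike-in brightness as a covariate 56246 probes were higher and 44016 lower. With the term for the late-scanned slides 47595 were higher and 26277 lower. The higher share of the calls was 51.4%, against 67.9% with median centring, a shift of the median change by 0.33 log2, and 62.2% without the filter on dim probes. More probes were lower than higher at changes of at least 2-fold (44238 higher and 47385 lower), with quantile normalization (57546 and 58883) and with only the 2 groups fitted (56628 and 58190).

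At 7 dpa, 47211 probes were higher and 32882 lower than in the uninjured limb, 34.2% of those tested. At least 8-fold changes were called for 2838 higher and 2074 lower probes. CUST_210579_Unique, not well above background in the uninjured limb or at 1, 3 or 5 dpa, had come above it on all 3 arrays and was at least 5.19-fold higher (adjusted p = 6.64e-09). CUST_24191_Unique was above background on no 7 dpa array and at least 104-fold lower. The groups did not overlap for 45.3% of probes. The higher share of the calls was 58.9%, against 70.5% with median centring, a shift of 0.18 log2.

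At 10 dpa, 50565 probes were higher and 33617 lower than in the uninjured limb, 36.0% of those tested. At least 8-fold changes were called for 3043 higher and 2376 lower probes. CUST_210579_Unique was at least 62.6-fold higher (adjusted p = 9.67e-12), and CUST_88938_Unique was at least 4.66-fold above the uninjured level (adjusted p = 1.63e-06). The groups did not overlap for 112180 probes. The higher share of the calls was 60.1%, against 72.7% with median centring, a shift of 0.23 log2.

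At 14 dpa, 54974 probes were higher and 59393 lower than in the uninjured limb, 48.9% of those tested. At least 8-fold changes were called for 4288 higher and 3011 lower probes. CUST_210579_Unique, the probe with the largest fitted rise, was at a level of 6.01 ± 0.45 log2 (SD, n = 3), at least 440.2-fold above the uninjured limb (adjusted p = 2.45e-13). CUST_24191_Unique, the probe with the largest fitted fall, was at 3.99 ± 0.05 log2 in the uninjured limb and not well above background on any 14 dpa array, at least 113-fold lower (adjusted p = 2.75e-10). After normexp their fitted log2 changes were 6.39 and -4.28. CUST_88938_Unique was still higher than in the uninjured limb, by at least 1.77-fold (adjusted p = 0.00321). The groups did not overlap for 52.4% of probes. Without array 3 of 14 dpa, 57499 probes were higher and 44803 lower, so that the higher share of the calls rose from 48.1% to 56.2% and the majority turned from lower to higher. It was 58.6% with median centring, a shift of the median change by 0.17 log2, and normexp shifted that median by 0.14 with a higher share of 54.4%. The majority also turned without uninjured replicate 1 (51085 higher and 48977 lower) or 2 (50507 and 49332), at an adjusted p under 0.01 (44046 and 36577), among probes above background on all 21 arrays (43322 and 30990) and with only the 2 groups fitted (41565 and 40067). It turned on early-scanned arrays alone (59843 and 54028), a set that likewise leaves out array 3 of 14 dpa.

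**Figure D2:**
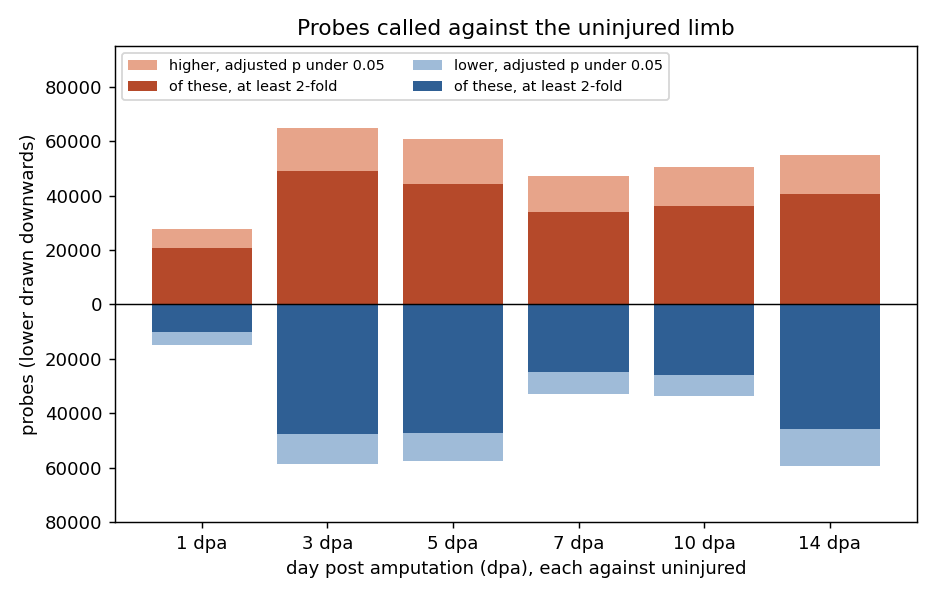
Number of probes called higher (upward bars) and lower (downward bars) than in the uninjured limb at each day, at an adjusted p under 0.05, with the dark part of each bar for changes of at least 2-fold. The upward bars are longest at 3 dpa (64918 probes), the downward bars at 14 dpa (59393, against 58493 at 3 dpa), and both are shortest at 1 dpa (27683 and 14857). At 14 dpa more probes are lower (59393) than higher (54974), a majority that turns in several alternatives, among them array 3 of that day left out (44803 and 57499).

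**Figure D3:**
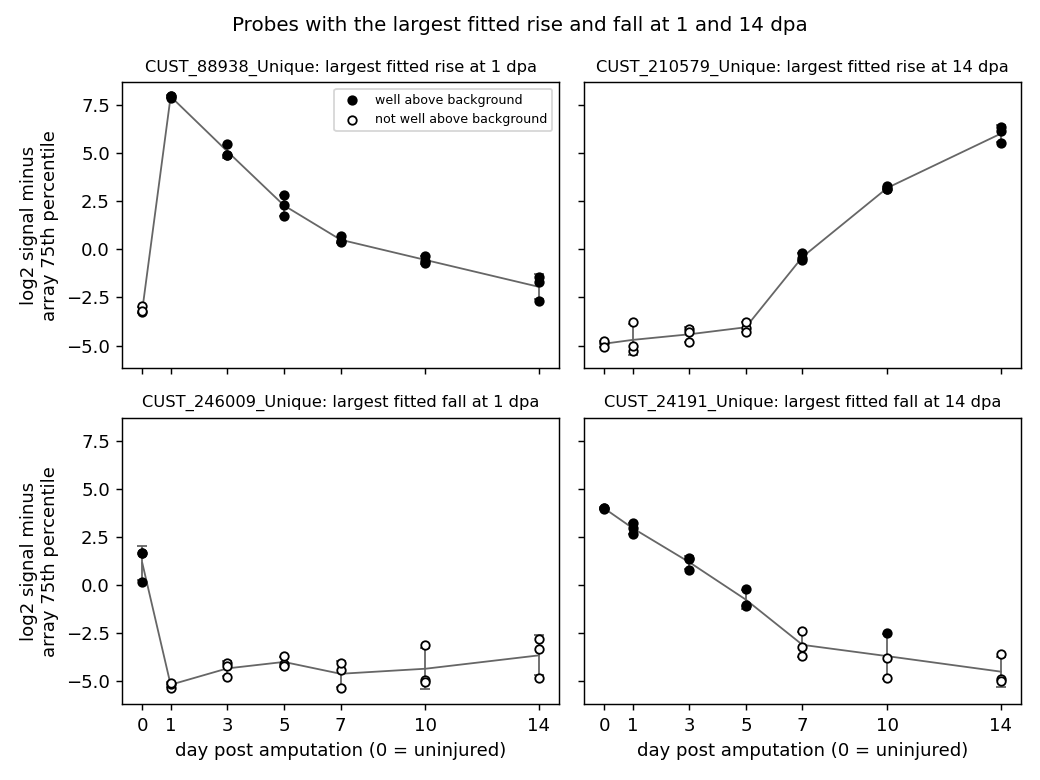
Log2 signal minus the array's 75th percentile for 4 probes against day post amputation, with 1 point per array, filled where the probe was well above background, a line through the group means and bars of 1 SD. CUST_88938_Unique peaks at 1 dpa at 7.94 and declines to -1.95 at 14 dpa, CUST_210579_Unique rises from 7 dpa on to 6.01, CUST_246009_Unique is open-marked on every day after amputation, and CUST_24191_Unique declines from 3.99 to -4.50.

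Successive days were compared to see when levels moved. Between 1 and 3 dpa 99717 probes changed, 55027 upward and 44690 downward, a higher share of 55.2% that was 73.2% with median centring and 47.4% among changes of at least 2-fold. With spike-in brightness as a covariate 66580 changed, and with a term for the late-scanned slides 52494, of which 72.6% were higher. Between 3 and 5 dpa 7175 probes changed, and 5433 of them fell. The higher share there was 24.3%, and 14.1% after normexp. On the slide that held both days, 2471 of 2780 probes called without its 2 arrays (88.9%) moved the same way. Slide as a fixed block left 902 calls, whose changes are estimated from those 2 arrays alone. The count was 3264 and 2609 without 3 dpa replicates 1 and 2, and 4020, 2244 and 4666 without 5 dpa replicates 1, 2 and 3. It was 13030 without 14 dpa replicate 3, an array of neither day in the shared fit, and 1209 with only the 2 groups fitted.

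Between 5 and 7 dpa 24368 probes changed, 10027 upward and 14341 downward, a higher share of 41.1% that was 25.5% with median centring. Without 7 dpa replicate 3, the late-scanned one, 48582 probes were called, without replicates 1 and 2 4901 and 4730, without 5 dpa replicates 2 and 3 7972 and 7088, and without 14 dpa replicate 3 39467. With only the 2 groups fitted 6223 were called, with slide as a random block 3857 and after normexp 63665. With spike-in brightness as a covariate the count was 8439, and with a term for the late-scanned slides 6749, of which 28.9% were higher. Between 7 and 10 dpa 2406 probes changed, and 1784 of them fell. On the slide that held both days, 445 of 479 probes called without its 2 arrays (92.9%) moved the same way. Slide as a fixed block gave 2881 calls, whose changes are estimated from those 2 arrays alone. Without 7 dpa replicates 1, 2 and 3 the count was 880, 1184 and 1448, and without 10 dpa replicates 1 and 2 896 and 883. It was 5194 without 14 dpa replicate 3 and 19 with only the 2 groups fitted. Between 10 and 14 dpa 14908 probes changed, 5938 upward and 8970 downward, with 9639 and 7226 without 10 dpa replicates 2 and 3, 5092 with slide as a random block and 1582 with only the 2 groups fitted. The higher share of 39.8% was 55.5% without array 3 of 14 dpa and 74.0% after normexp, so the direction of the majority turned.

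Levels that stayed on one side of the uninjured limb were mostly above it. On all 6 days 15546 probes were higher, where independent lists of these sizes would share 20.5, and 3620 were lower, where they would share 4.70. Unchanged groups simulated against the same controls, with lists of these sizes taken by the moderated t, shared 1.98% and 1.07% of the tested probes, against 6.65% and 1.55% observed. These lists were filled with noise to the real lengths, and at the adjusted p used for the real lists the simulation gave 0 for both counts. It therefore cannot tell how much of the counts comes from the controls that all 6 comparisons share, and no excess is claimed. The 3 control arrays are too few to split. A difference in limb position of the uninjured tissue, which the labels leave unsettled, would also enter on all 6 days. The lower count was 1868 with median centring and 6616 with quantile normalization, and the higher count was 15082 and 15558.

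Early changes were compared with the levels at 14 dpa. Of the 27683 probes higher at 1 dpa, 10687 were lower at 14 dpa than at 1 dpa, of which 6343 were not called against the uninjured limb at 14 dpa, 2367 were still higher than in it and 1977 had come to lie below it. Independent lists would share 6302. Of the 14857 probes lower at 1 dpa, 8335 were higher at 14 dpa than at 1 dpa, where independent lists would share 3070. At the late end, 14473 probes were higher at 14 dpa than both in the uninjured limb and at 3 dpa, and 12844 of these had not been called higher at 1 dpa. Another 23698 were lower at 14 dpa than in both, and 15085 after normexp. Independent lists would share 7302 and 12493. Both comparisons behind each of these 4 counts share the arrays of 1 day. Unchanged groups simulated on the same design, with lists of the same sizes, shared 15178, 8721, 16714 and 25357 in the order given, all above the counts observed. Those lists were filled with noise to the real lengths, and at the adjusted p used for the real lists the same simulation gave 0 for each count. The simulation therefore cannot tell how much of the counts comes from shared arrays, and no excess over independent lists is claimed. Without array 3 of 14 dpa these late counts were 17931 and 20077.

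**Figure D4:**
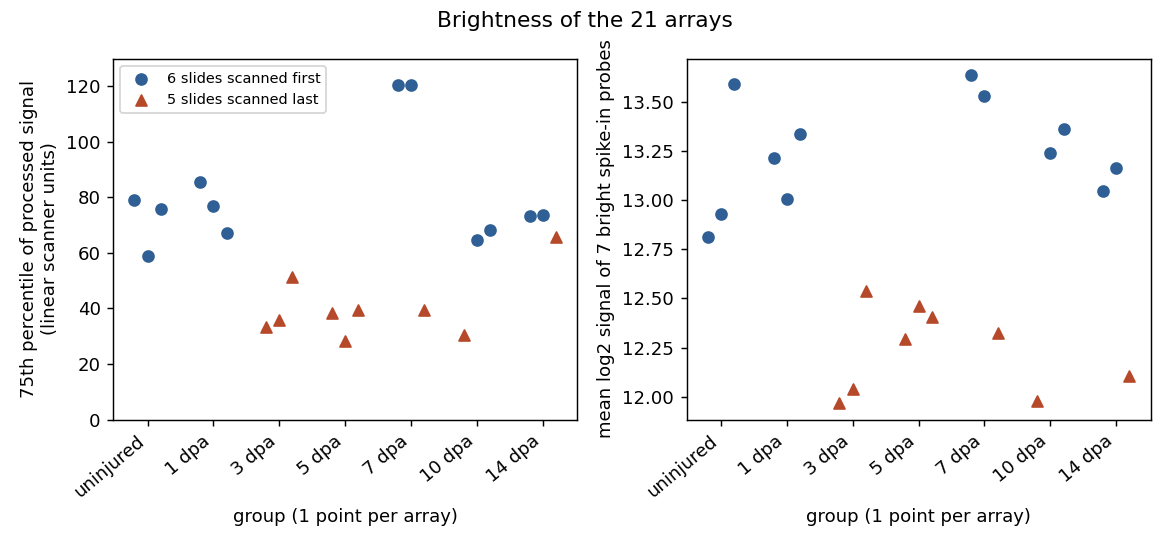
Left, the 75th percentile of the processed signal in linear scanner units, and right, the mean log2 signal of 7 bright spike-in probes, with 1 point per array by group, circles for the 6 slides scanned first and triangles for the 5 scanned last. Late-scanned arrays have spike-in levels of 11.97 to 12.54 and early-scanned arrays 12.81 to 13.64, and all arrays of 3 and 5 dpa are late.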

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

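The tests of brightness, of the late-scanned slides, of the deposited row names and of array 3 of 14 dpa were chosen only after the patterns were seen. The counts over other splits of the arrays were planned before. Levels differed between successive days, by limma's contrast of those days, for 99717 probes between 1 and 3 dpa, 7175 between 3 and 5 dpa, 24368 between 5 and 7 dpa, 2406 between 7 and 10 dpa and 14908 between 10 and 14 dpa. With each replicate of the 2 days compared left out in turn, these counts ranged from 71656 to 89202, 2244 to 5153, 4730 to 48582, 880 to 1840 and 7226 to 13159. The low ends were without 1 dpa replicate 1, 5 dpa replicate 2, 7 dpa replicate 2, 7 dpa replicate 1 and 10 dpa replicate 3, and the 48582 was without 7 dpa replicate 3. Without 14 dpa replicate 3 the first 4 counts were 111632, 13030, 39467 and 5194, and other arrays outside the days compared were not left out.

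The 6 arrays of 2 groups can be split in 10 ways, the real one included, which is too few for a share under 0.05. In each of the 11 comparisons of 2 groups the real split was the 1 of 10 with the most calls. The highest other split gave 1, 2, 0, 460, 1 and 1729 calls for the 6 days in order against the uninjured limb, where the real counts were 42540, 123411, 118513, 80093, 84182 and 114367. For the successive days in order it gave 0, 5, 91, 0 and 2. For the F test over all days, 1 of 100 drawn splits of the 21 arrays, the real one, reached 168838 probes, and the highest other gave 20693. This argues against a freely drawn division of the arrays. The draws did not keep arrays of a slide together, as the real groups do, so they cannot tell a division by day from one by slide.

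Changes at 3 and 5 dpa coincide with dim arrays scanned late. If they followed brightness alone, little of a change of at least 2-fold would be left with spike-in brightness in the model, and arrays simulated that way kept 0.0745 and 0.119 of it. The data kept 0.912 at 3 dpa and 0.932 at 5 dpa against the uninjured limb, 0.856 for 3 against 1 dpa and 0.785 for 7 against 5 dpa, which argues against a linear brightness effect as the whole cause (probes were taken by the size of change, since calls favour probes with a small brightness slope). A term for the late slides, estimated from 3 late arrays on 2 slides at 7, 10 and 14 dpa, left 0.848, 0.847, 0.760 and 0.696 (at least 0.629 from any 1 of those arrays), where arrays simulated with only such a difference kept 0.0743 to 0.156, so a difference shared alike by all late slides is argued against as the whole cause, though the probes lower at 3 dpa fell in number from 58493 to 27531 with it. What stays open is a difference of the 3 slides of 3 and 5 dpa from the other late ones, which cannot be told apart from these days since they hold no other group, and a biological change, which may explain the rest.

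The names in the deposited table do not belong to the values beside them. Probes with adjacent ID numbers correlated at a median of 0.679 over the arrays under the scanner names and 0.0051 under the table's names, as a shift of the table's names would give. A shift of the scanner names instead would put ordinary probes in the negative-control positions, yet 0.242% of negative-control spots were well above background, against 49.4% of other probes. A candidate explanation is that the first 2 probes were dropped from the names but not from the values. No row bears the names of these 2, and their values stand beside the names of later probes. No biological explanation was tested.

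Array 3 of 14 dpa had 21591 probes above background that were above it on no other array, against 113 to 2241 on each of the others, and 1610 non-uniform spots against 3 to 31, of which 599 were among those probes. Damage in one area of the array was argued against by a highest correlation between neighbouring spots of 0.0066 for those probes (0.0043 for the non-uniform spots). The negative-control median was 2.32, within the 2.05 to 2.94 of the other 20 arrays. That median was taken on background-subtracted signal. It argues against a raised background left after subtraction and cannot show one that subtraction removed. Low signals lifted in labelling or hybridization would raise dim spike-ins against bright ones, and that difference lay 1.29 log2 above the highest other late-scanned array. It rests on 3 dim and 7 bright spike-in probes. A lift of low signals is consistent with these values, and a difference in that batch of animals may add to it but was not tested.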

How the results depend on the processing

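The 4 named probes kept direction and call in all 58 values they had under alternatives, replicates left out aside. They were chosen for the largest fitted changes in the same arrays, so this was likely in advance and does not test other probes. The filter to probes above background on all 21 arrays removed all 4, and normexp narrowed their log2 changes to 7.92, 6.39, -2.05 and -4.28. Of 279 counts under alternatives, 228 lay within 1.5 times the reported count, 46 fell below and 5 rose above. Of 78 counts that combine days, 65 lay within that range, 12 fell below and 1 rose above. Both sets include the deposited log2 table, which in nearly all rows equals the main values up to a constant per probe. Its counts therefore had to lie close to the reported ones and test little. Alternatives chosen after seeing the data were spike-in brightness, the term for late-scanned slides, early-scanned arrays, slide as a fixed block and array 3 of 14 dpa left out. Averaging the sense probes of a gene and the gene list tests were not run, since the IDs are unnamed. The 101850 probes above background on no array gave no level. Apart from smaller sets of probes or arrays the cause of a shift was not tested.

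An adjusted p under 0.01 left 8721, 37994, 37091, 20116, 21077 and 36577 probes lower than in the uninjured limb on the 6 days in order. Between successive days it left 62359 (1 to 3 dpa), 1906 (3 to 5), 4702 (5 to 7), 681 (7 to 10) and 5405 (10 to 14). Median centring gave 33842, 35682, 21559 and 21685 lower probes at 3, 5, 7 and 10 dpa, and 3312, 1001 and 9109 changed from 3 to 5, 7 to 10 and 10 to 14 dpa. Normexp gave 34894 and 35850 lower probes at 3 and 5 dpa, and 63665 and 3727 changed from 5 to 7 and 7 to 10 dpa. Only the 128581 probes above background on all 21 arrays, a smaller set, gave 24327, 23724, 17397, 16425 and 30990 lower probes at 3, 5, 7, 10 and 14 dpa and 106162 changed on any day. Without a filter on dim probes 2816, 10632, 1082 and 8465 changed from 3 to 5, 5 to 7, 7 to 10 and 10 to 14 dpa, and with only the 2 groups compared, hence fewer arrays, 1209, 6223, 19 and 1582.

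Slide as a random block (correlation 0.497) gave 21844 lower probes at 7 dpa, and 3857 and 5092 changed from 5 to 7 and 10 to 14 dpa. Slide as a fixed block, where each change is estimated from the 2 arrays of a shared slide alone, gave 17339 higher probes at 1 dpa and 902 changed from 3 to 5 dpa. Spike-in brightness gave 8439 from 5 to 7 dpa. The term for late-scanned slides gave 27531 and 26277 lower probes at 3 and 5 dpa, and 52494 and 6749 changed from 1 to 3 and 5 to 7 dpa. Early-scanned arrays alone gave 1180 and 8625 from 7 to 10 and 10 to 14 dpa. Array 3 of 14 dpa left out of the shared fit gave 13030, 39467 and 5194 from 3 to 5, 5 to 7 and 7 to 10 dpa. With each replicate of the 2 days compared left out, the ranges were 2244 to 5153 from 3 to 5 dpa, 4730 to 48582 from 5 to 7, 880 to 1840 from 7 to 10, and 7226 to 13159 from 10 to 14.

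Of the counts that combine days, changes of at least 2-fold left 9307 probes higher and 2161 lower on all 6 days, and an adjusted p under 0.01 left 1835 lower. Median centring gave 1868 and quantile normalization 6616 of the latter. Probes lower at 1 dpa and higher at 14 than at 1 dpa numbered 5149 at 2-fold and 4932 at an adjusted p under 0.01. Probes higher at 14 dpa than both in the uninjured limb and at 3 dpa numbered 8723 at 2-fold, 8825 at an adjusted p under 0.01 and 9247 with slide as a random block. Those lower than both numbered 15174, 14066 and, after normexp, 15085.

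The replicate numbers were not taken to pair the arrays, since the labels do not say that a number stands for the same batch of animals across days. Deviations from the group means correlated from -0.348 to 0.366 over 63 pairs with the same number and different days, 22 of them above 0.1 (median 0.0429), against 22 of 126 pairs with different numbers (median -0.0106), and for 7 of 21 arrays the best partner had the same number. With a replicate block every count stayed within 1.5 times, for example 27827 higher probes at 1 dpa and 171515 changed on any day.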

Other observations

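Most large changes were furthest from the uninjured limb at 3, 5 or 14 dpa. Of 56305 probes that changed over the course and reached at least 4-fold on some day, 28444 were furthest above the uninjured limb and 27861 furthest below it. The numbers furthest above on the 6 days in order, from 1 to 14 dpa, were 3055, 8845, 5355, 635, 1675 and 8879, and those furthest below were 1369, 8873, 6009, 2218, 2555 and 6837. After normexp, whose offset narrows the folds of dim probes, 12239 probes reached 4-fold, 8270 furthest above and 3969 furthest below. Of these, 1342 were furthest above and 125 furthest below at 1 dpa, against 662 and 623 at 5 dpa. Among probes above background on all 21 arrays 24003 reached 4-fold, 17040 above and 6963 below. There the numbers were 1287 and 514 at 1 dpa, against 2952 and 751 at 5 dpa. With median centring 15670 were furthest above and 4425 furthest below at 3 dpa, with spike-in brightness as a covariate 8652 and 4475, and with a term for the late-scanned slides 9145 and 3202. Without array 3 of 14 dpa the numbers at 14 dpa were 11006 above and 6158 below. In all, 10194 probes were called in opposite directions on 2 days, among them 2698 lower at 1 dpa and higher at 14 dpa.

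Probe IDs end in the name of 1 of 9 probe sets, and the labels do not say what each set holds. The sets PI433099070 and PI433099144 were mostly dim, with 31.3% and 30.9% of their probes tested, against 93.2% of PI256121980. At 3 dpa 1943 tested probes of PI433099070 were higher and 7115 lower than in the uninjured limb, 1222 and 6591 of PI433099144, and 7049 and 1411 of PI256121980. At 3 dpa these majorities held with median centring (2817 and 4420, 1944 and 4146, 8132 and 664), with normexp (2132 and 2973, 1413 and 2821, 6125 and 1402) and with quantile normalization (2105 and 5998, 1363 and 5557, 6130 and 2026). They held with smaller numbers under a term for the late-scanned slides (1411 and 2809, 884 and 2489, 6428 and 594) and among probes above background on all 21 arrays (1097 and 2117, 725 and 1966, 6613 and 1003). They also held without the filter on dim probes, where the dim sets' numbers of higher probes came to 4481 and 3381 beside 7039 and 6536 lower. On other days those of the dim sets did not all hold. At 1 dpa both had more higher than lower probes (920 and 691, 545 and 509), which for PI433099144 turned with, among others, normexp (388 and 424) and spike-in brightness (617 and 632). At 5 dpa the majority of PI433099070 turned with normexp (2589 and 2490), and those of both dim sets without the filter on dim probes (10703 and 6235, 9142 and 5770). With median centring both turned at 7 dpa (1745 and 1332, 1156 and 1089) and at 10 dpa (1947 and 1367, 1371 and 1140). Among probes above background on all 21 arrays PI433099070 turned at 7 dpa (855 and 729) and both at 10 dpa (969 and 672, 680 and 536). Probes above background on array 3 of 14 dpa alone made up 8.85% and 8.39% of the PI433099070 and PI433099144 probes, and 0.575% of PI256121980.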
